A study of Homo sapiens with 16 samples.

How the data were processed

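RNA-seq of human fetal liver and adult bone marrow CD34+ HSPCs and ProEs, 16 libraries in 4 groups of 4, was analysed from a table of counts and a table of RPKM. Per the labels' protocols, total RNA was made into TruSeq RNA v2 libraries and sequenced on an Illumina HiSeq instrument. The deposited counts are whole numbers per gene symbol with no scaling, 1 column per library. Per the submitters' processing notes, TopHat, DESeq and the build hg18 were used, without versions or roles, and the program that counted reads is not stated. The deposited RPKM values are counts scaled by gene length and library total. The gene length implied by count and RPKM varied by over 10% between libraries for 375 of the 8220 genes above 100 counts in every library, and 0% of the values had a 0 in only 1 of the tables.

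The table held 21490 symbols, of which 18029 are current RefSeq symbols, 2736 are only older symbols and 26 had been turned into dates by a spreadsheet. The reference annotation is of another build than the files, so it served for symbols only and no coordinates are given. XIST, TSIX and 101 sex-linked genes in all, Y-linked genes included, were removed before any test. Another 2272 genes had no count in any library. Total counts were 23357934 to 30293979 in replicates 1 and 2 and 8156963 to 13476125 in replicates 3 and 4. No intervals are given for single libraries, because group values carry the spread between samples.

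Replicates of a group were compared by a chi-square per gene with a summed count of at least 20. Pairs with a median below 1 (0.4549 from sampling alone) were summed and counted as 1 sample. That joined replicates 1 and 2 in every group and replicates 3 and 4 in both HSPC groups, leaving 10 samples. The limit of 1 was chosen after the replicates were seen, and the planned fit counted all 16 libraries separately. Values of that fit are printed beside the counts.

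Differential expression was tested with edgeR 4.0.16 in R 4.3.3 with the quasi-likelihood test, TMM scaling, 1 coefficient per group over all 10 samples, and 6 residual degrees of freedom. The function filterByExpr kept 15522 genes, and the common biological coefficient of variation was 0.33. The 4 comparisons were ProE against HSPC within each stage and adult against fetal within each cell type, and the interaction was the adult minus the fetal differentiation change. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. CPM are TMM-scaled means of the combined samples, with the SD over them. The 25 gene lists, fixed before the files were opened, were tested with camera (limma 3.58.1, after voom) at a preset correlation of 0.01 and again with an estimated correlation, if at least 3 members were tested. Globin shares were compared by exact two-sided permutation tests on the combined samples, with Benjamini-Hochberg adjustment over 4 tests. Principal components used log2 CPM of the 16 libraries. Overlaps of calls are given with the product of both list sizes over the genes tested.

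The named genes followed a rule fixed in advance. Each comparison names the 4 largest rises and 4 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. It also names, for the 5 called lists with the smallest camera p, the 2 members with the smallest adjusted p moving in the list's direction. The key genes reported were HBG1, HBG2, HBB, HBE1, LIN28B, IGF2BP1, BCL11A, GATA1, GATA2, KLF1, MYB, SPI1 and CD34. For the interaction, the 4 largest positive and 4 largest negative called terms with a mean of at least 10 CPM in some group were named. A pseudogene that the rule picked, whose presence varies between people, is left out, and a few other genes the rule named are not reported here. Other list members, such as ALAS2, SLC4A1, HFE, BCAM, KIT, HLF, S100A8, C1QA and HBZ, were chosen after their values were seen.

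The replicate numbers were checked for pairing. Deviations of same-numbered libraries from their group means correlated at 0.176 or more in all 24 pairs (median 0.455), so the numbers were taken to pair the samples. Other numbers of the same series had a median of 0.453, and a library's own number was its best match in 11 of 24 cases, so the pairing acts through the series. The other series had -0.445, which adds no evidence, because deviations from a group mean largely force it to mirror the same-series value. A fit with the series as a replicate block is therefore given where it changes a call or moves a count by over 1.5 times. A gene or list said to pass only with the block failed on the 10 samples without it, and other alternatives may also call it. The pipeline was tested on simulated data with the same group sizes and known changes. At 2-fold, 2 to 10 of 82 were recovered, depending on the comparison, and at 8-fold 45 to 58 of 59, with 4 to 10 false calls. The simulated samples were drawn independently, with no difference between the series, so these rates need not hold for the real samples.

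Alternatives were DESeq2 size factors, library totals, removal of globin genes, no low-count filter, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, only the 2 groups compared, and limma on log2 RPKM with a pseudocount of 1 or 0.1 and a mean RPKM of at least 0.5 or no filter. Replicate blocks, other ways of combining replicates, the second series alone, and leaving out each library or combined pair were tried as well. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables and figures.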

Results

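RNA was sequenced from human primary CD34+ hematopoietic stem and progenitor cells (HSPCs) and from proerythroblasts (ProEs), the earliest recognisable red cell precursors. Cells came from fetal liver or adult bone marrow and were grown and differentiated in serum-free liquid culture. The 16 libraries form 4 groups of 4: fetal HSPC, fetal ProE, adult HSPC and adult ProE. The design addresses how expression changes as progenitors become ProEs, how fetal and adult cells differ at each step, and whether the differentiation change differs between the stages. Total counts ranged from 23357934 to 30293979 in replicates 1 and 2 of every group, here called the first series. They ranged from 8156963 to 13476125 in replicates 3 and 4, the second series.

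Replicates 1 and 2 differed by little more than sampling noise in all 4 groups, and so did replicates 3 and 4 of both HSPC groups. Their median chi-square per gene was 0.555 to 0.670, against 0.455 from sampling alone and 2.64 or more for all other pairs of a group. Each such pair was summed and counted as 1 sample, which left 10 samples: 2 fetal HSPC, 3 fetal ProE, 2 adult HSPC and 3 adult ProE. Each HSPC group then held 1 sample per series, and each ProE group 1 of the first and 2 of the second. Values of ProE against HSPC without a block by series therefore carry part of any difference between the series. Combining departs from the fit of 16 libraries planned before the data were examined, and its threshold was chosen after the replicates were seen. The labels do not say that replicates came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be technical. The 16 libraries separated by cell type and stage on components 1 and 2, which held 44% and 19.2% of the variance. Component 3, with 13.4%, separated the series.

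**Figure D1:**
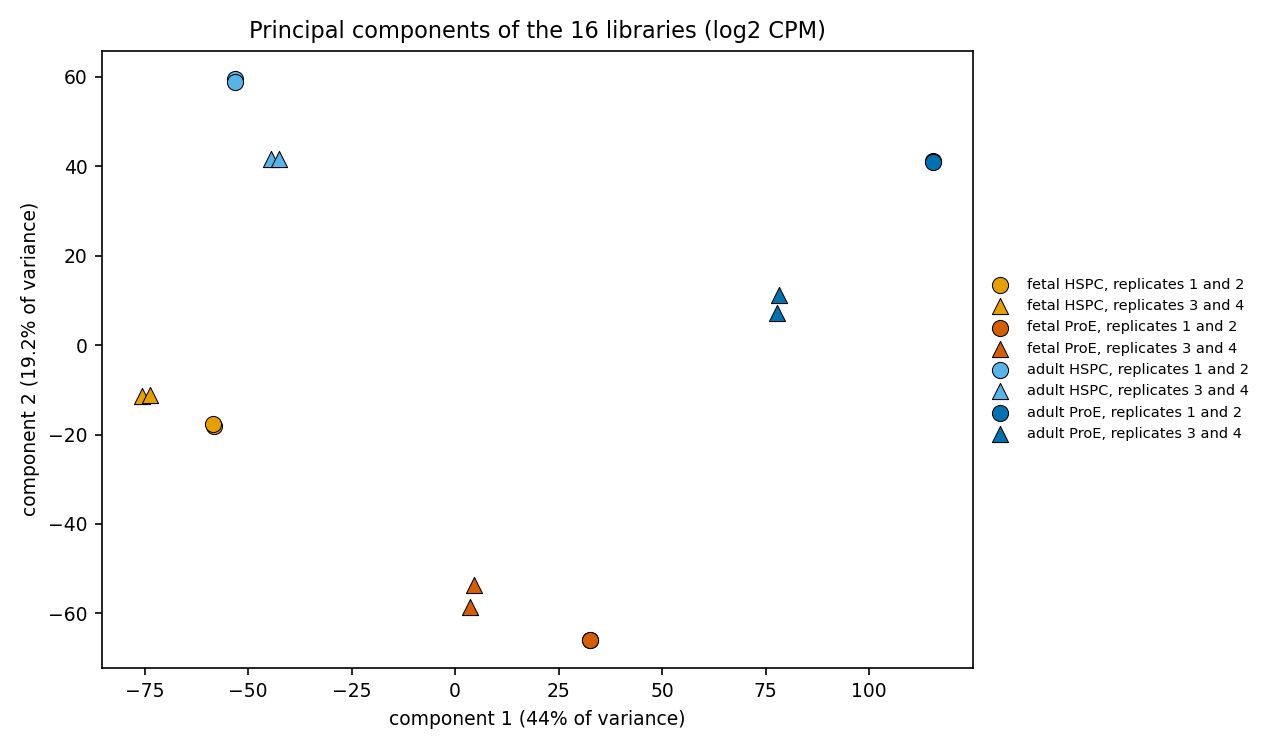
Principal components 1 and 2 of log2 CPM (counts scaled by library total) of the 16 libraries, as percent of variance on each axis, with 1 point per library coloured by group. Component 1 (44%) ran from HSPC to ProE libraries, and component 2 (19.2%) parted adult from fetal libraries.

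In fetal cells, some genes of red cell membrane, heme synthesis and erythroid transcription were higher in ProEs than in HSPCs, and some antigen presentation and interferon genes lower. As lists, these changes passed only with a preset correlation between genes, and not with an estimated one. The transferrin receptor TFR2 rose from 42.2 ± 4.08 (SD, n = 2) to 307 ± 19.3 CPM (SD, n = 3), a log2 fold change of 2.86 ± 0.21 (SE, edgeR adjusted p = 0.000696). CPM are counts scaled by library total. The erythroid regulators GATA1, KLF1 and GFI1B rose by 2.10, 2.62 and 2.43 on the log2 scale (edgeR adjusted p = 0.0044, 0.0054 and 0.00429). PPOX, an enzyme of heme synthesis, rose by 2.08, and ICAM4 and RHD, which encode blood group proteins, by 2.38 and 3.84. CD34, the surface marker of the starting cells, fell by 4.07 on the log2 scale, from 65.4 ± 38.6 (n = 2) to 4.14 ± 2.94 CPM (n = 3; edgeR adjusted p = 0.031). The largest rises by the naming rule included HIF3A (log2 5.78), CHIT1 (5.74), LOC100131726 (5.70) and TEAD1 (5.62). The largest falls included STEAP4 (-5.97), IRF4 (-5.64) and NRP1 (-5.27). GATA2 (-0.24), MYB (-0.06), BCL11A (-1.13), SPI1 (-0.39), LIN28B (-0.34) and IGF2BP1 (-0.27) did not pass (edgeR adjusted p = 0.221 to 0.912).

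By gene list, 13 of 26 red cell membrane and surface genes rose and 1 fell (21 and 2 adjusted over the list alone). The one that fell, BCAM (-4.04), encodes a surface adhesion molecule. In heme synthesis and iron handling, 12 of 21 rose and 1, the iron regulator HFE (-3.13), fell (16 and 1 adjusted over the list alone). Of 17 erythroid transcription factors 9 rose and 0 fell (13 and 0 adjusted over the list alone). These lists had camera adjusted p = 6.91e-13, 1.72e-12 and 1.28e-09, against adjusted p = 0.206, 0.206 and 0.204 with an estimated correlation. MHC class II genes fell in 10 of 11 cases (11 adjusted over the list alone), including the class II activator CIITA (-4.30) and HLA-DMB (-5.09). Interferon response genes fell in 10 of 24 (19 adjusted over the list alone), among them the antiviral sensor OAS3 (-3.28) and XAF1 (-2.59). Their camera adjusted p = 7.71e-12 and 1.74e-12, and adjusted p = 0.206 for each with an estimated correlation. Stem and progenitor genes fell in 6 of 27, including RUNX1 (-1.23) and HLF (-2.79), and 1, MLLT3 (1.28), rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.00901, adjusted p = 0.37 with an estimated correlation). With the replicate block by series, 20 membrane genes rose, 19 interferon genes fell, and 11 stem and progenitor genes fell and 2 rose.

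Markers of other cell types also moved with fetal differentiation. Of 9 tested macrophage genes 1 fell, the mannose receptor MRC1 (log2 -4.53), from 244 ± 64.8 (n = 2) to 10.5 ± 2.89 CPM (n = 3), and 5 fell adjusted over the list alone. The macrophage list had camera adjusted p = 0.0417, adjusted p = 0.681 with an estimated correlation and 0.0918 with the replicate block by series. Lymphoid genes fell in 2 of 12, IL7R (-4.74) and BLNK (-4.71), with 3 adjusted over the list alone (camera adjusted p = 0.0362, adjusted p = 0.548 with an estimated correlation). Of 21 granulocyte and monocyte genes 0 passed by edgeR (4 fell and 1 rose with the replicate block), although the means of S100A8 were 138 ± 40.6 in HSPC and 1183 ± 696 CPM in ProE. Of 16 HOXA and HOXB genes 1 fell, HOXB5 (-2.96), with 7 adjusted over the list alone (camera adjusted p = 0.00482, adjusted p = 0.553 with an estimated correlation). DNA replication genes passed as a list that rose slightly (median log2 0.23, 0 of 23 called, 0 adjusted over the list alone, 1 with the block; camera adjusted p = 0.0329, or 0.0156 with the block and adjusted p = 0.616 with an estimated correlation). Mitosis genes did not pass as a list with the 10 samples and no block (0 of 23 called, 0 adjusted over the list alone, camera adjusted p = 0.11, or 0.693 with an estimated correlation). They passed as a list with the replicate block and with the 16 libraries counted separately (camera adjusted p = 0.0342 and 0.0227). With the block, 5 lymphoid and 8 HOXA and HOXB genes fell, 2 macrophage genes fell and 1 rose, and 1 mitosis gene rose.

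In this comparison edgeR called 430 genes higher and 597 lower among 15522 tested, 1101 and 1484 with the replicate block by series, and 1764 and 2202 with the 16 libraries counted separately. In simulated data with these group sizes, few changed genes and no difference between the series, 7 of 82 genes changed 2-fold and 48 of 59 changed 4-fold were recovered. Leaving out fetal HSPC replicates 1 and 2, fetal HSPC replicates 3 and 4, fetal ProE replicates 1 and 2, fetal ProE replicate 3 or fetal ProE replicate 4 left 157, 132, 245, 244 and 224 genes higher and 240, 187, 242, 198 and 273 lower. CHIT1, IRF4, NRP1, XAF1, TEAD1, ICAM4 and CD34 each lost the call in at least 1 of these fits (highest edgeR adjusted p = 0.216, 0.0651, 0.0677, 0.0618, 0.0809, 0.0504 and 0.12).

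In adult cells, many erythroid genes were also higher in ProEs, and many genes of cell division lower, with no list passing at an estimated correlation. PPOX rose from 18.1 ± 2.27 (n = 2) to 181 ± 12.5 CPM (n = 3), a log2 fold change of 3.32 ± 0.22 (SE, edgeR adjusted p = 0.000201). KLF1, GATA1 and TFR2 rose by 2.58, 1.73 and 2.25 on the log2 scale (edgeR adjusted p = 0.0014, 0.00192 and 0.000382). The progenitor regulator GATA2 fell by 2.24 on the log2 scale, from 300 ± 21.4 (n = 2) to 63.8 ± 11 CPM (n = 3; edgeR adjusted p = 0.00112). CD34 changed by -4.09 and MYB by -0.83 (edgeR adjusted p = 0.0114 and 0.0116). FMOD (log2 7.20), IFI27 (6.71), CALB1 (6.69) and ITLN2 (6.66) rose most by the naming rule, and CHRNA6 (-7.19), LUM (-6.74), JPH1 (-5.98) and THSD7A (-5.54) fell most. FMOD moved to 11.7 without adult HSPC replicates 3 and 4 and LUM to -11.7 without adult ProE replicate 3, where the samples left in that group held 0 counts, so these values give no size. SPI1, a myeloid regulator, had a log2 fold change of -1.56 that passed only with the replicate block (edgeR adjusted p = 0.172, or 0.00134 with the block). LIN28B (0.92), IGF2BP1 (0.92) and BCL11A (0.59) did not pass (edgeR adjusted p = 0.428 to 0.567). Within the first and second series LIN28B changed by 0.03 and 0.64, and IGF2BP1 by 0.36 and 0.58, all less than the 0.92 over all samples. LIN28B and IGF2BP1 were 2.78 and 3.61 without adult HSPC replicates 3 and 4, and 0.08 and 0.02 without adult HSPC replicates 1 and 2. Both fits leave adult HSPCs of a single series, so the difference between the series enters these values. BCL11A was 0.31 without adult ProE replicate 3 and 0.99 without adult ProE replicate 4.

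Of 21 heme and iron genes 18 rose and 0 fell (19 and 0 adjusted over the list alone), led by PPOX and TFR2, with ALAS2, the first enzyme of the pathway in red cells, at 5.02. Of 26 membrane and surface genes 21 rose and 0 fell (23 and 2 adjusted over the list alone), among them EPB42 (4.52), ERMAP (2.56) and the anion exchanger SLC4A1 (5.82). Of 17 erythroid transcription factors 13 rose and 1, MYB, fell (14 and 1 adjusted over the list alone). For these lists camera gave adjusted p = 1.37e-12, 4.25e-11 and 4.83e-08, against adjusted p = 0.163, 0.184 and 0.163 with an estimated correlation. Stem and progenitor genes fell in 18 of 27, including RUNX1 (-1.86) and ERG (-3.51), and 1 rose, the growth factor receptor KIT (3.02), which red cell precursors also carry (22 and 3 adjusted over the list alone). Mast cell, basophil and eosinophil genes fell in 9 of 15, including HDC (-4.15) and CPA3 (-3.76), with 10 adjusted over the list alone. The camera values were adjusted p = 5.57e-08 and 1.51e-05, against adjusted p = 0.163 and 0.347 with an estimated correlation. With the replicate block, 22 membrane genes rose and 2 fell, and 22 stem and progenitor genes fell and 2 rose.

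Mitosis genes fell in 19 of 23 (21 adjusted over the list alone), including the kinesin KIF20A (-1.62) and the spindle checkpoint kinase BUB1B (-1.49). DNA replication genes fell in 11 of 23 (14 adjusted over the list alone), including UHRF1 (-1.33) and TYMS (-1.06). Both lists passed by camera at adjusted p = 5.51e-10 and 4.25e-06, against adjusted p = 0.163 and 0.255 with an estimated correlation. Immediate early genes, which respond within minutes to stimuli, rose in 15 of 18 (15 adjusted over the list alone), including PPP1R15A (2.43) and BTG2 (2.85). Of 17 p53 targets 6 rose and 0 fell (6 adjusted over the list alone), among them TP53INP1 (2.98) and BBC3 (2.79). Camera gave adjusted p = 1.53e-08 and 0.00515 for these lists, against adjusted p = 0.214 and 0.163 with an estimated correlation. The replicate block gave 18 DNA replication genes that fell, and 8 p53 targets that rose and 1 that fell.

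Markers of macrophages and granulocytes moved with adult differentiation as well. Of 9 macrophage genes 5 rose (9 adjusted over the list alone), including the complement gene C1QA, from 1.14 ± 1.47 (n = 2) to 79.4 ± 74.1 CPM (n = 3), a log2 fold change of 6.21. The list had camera adjusted p = 0.00872, and adjusted p = 0.587 with an estimated correlation. Granulocyte and monocyte genes fell in 5 of 21, including MPO (-2.98) and CSF3R (-2.45), with 5 adjusted over the list alone (camera adjusted p = 0.0181, adjusted p = 0.652 with an estimated correlation). Glycolysis genes fell in 8 of 18, including LDHA (-2.03), and 3 rose, including SLC2A1 (2.88), with 9 and 4 adjusted over the list alone. That list did not pass with the 10 samples and no block (camera adjusted p = 0.0539, or 0.592 with an estimated correlation). It passed with the replicate block and with the 16 libraries counted separately (camera adjusted p = 0.0131 and 0.0488). Interferon genes, of which 4 rose and 5 fell (4 and 6 adjusted over the list alone), passed as a list with the block but not without it. Camera gave adjusted p = 0.0899, or 0.0416 with the block, 0.0898 with the 16 libraries and 0.652 with an estimated correlation. With the block, 12 interferon genes fell and 4 rose, and 11 granulocyte and monocyte genes fell and 1 rose.

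For adult ProE against adult HSPC, edgeR called 1756 genes higher and 1965 lower, 2918 and 3237 with the replicate block by series, and 3336 and 3559 with the 16 libraries counted separately. Leaving out adult HSPC replicates 1 and 2, adult HSPC replicates 3 and 4 or adult ProE replicate 4 left 712, 1030 and 1168 genes higher and 811, 1141 and 1175 lower. CALB1, ITLN2, MYB and CD34 each lost the call in at least 1 of these fits (highest edgeR adjusted p = 0.0515, 0.0835, 0.109 and 0.0636). In simulated data for this comparison, again with few changed genes and no series difference, 7 of 82 genes changed 2-fold and 42 of 59 changed 4-fold were recovered.

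Across the 15522 genes, 316 rose in both fetal and adult differentiation, against 48.6 for independent lists of these sizes, and 298 fell in both, against 75.6. Another 19 genes were called in opposite directions, and the log2 fold changes correlated at r = 0.506 across genes, which are not independent replicates. The comparisons share no library, but both use the same estimate of spread per gene and the same mix of series. Their lists are therefore not independent, and 48.6 and 75.6 serve only as a scale.

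**Figure D2:**
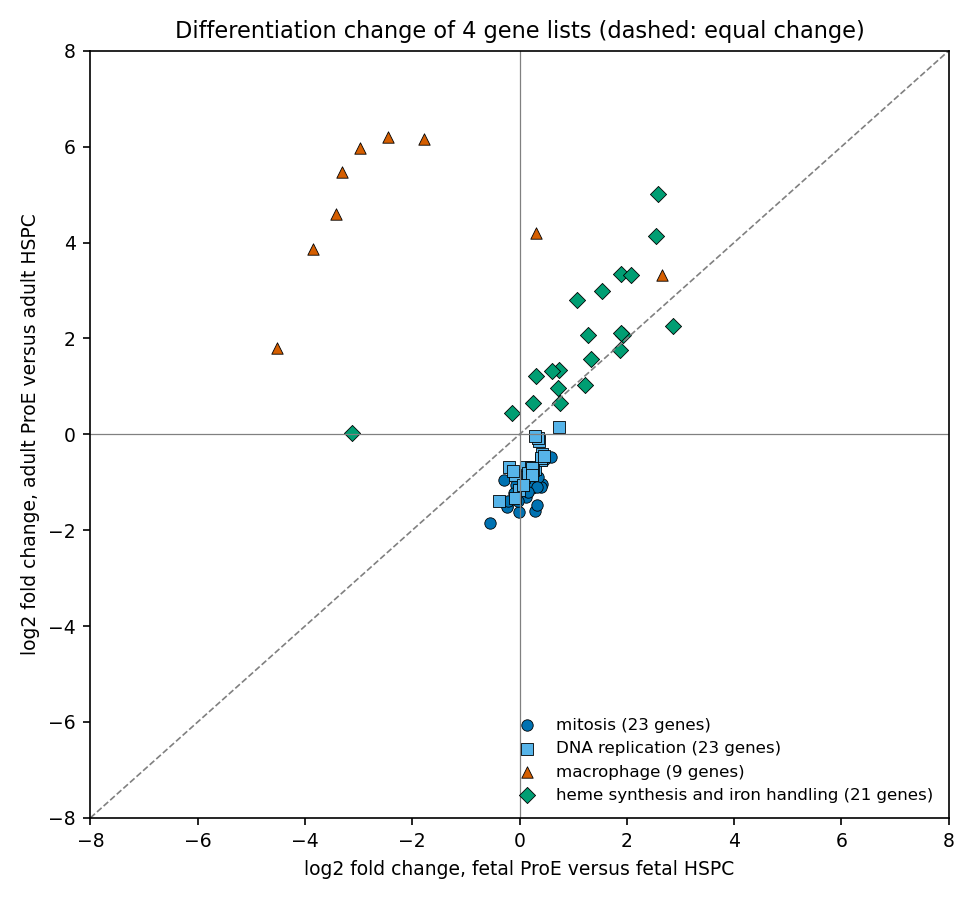
Log2 fold change from HSPC to ProE in fetal cells (horizontal axis) and adult cells (vertical axis) for the genes of 4 lists, with 1 point per gene and a dashed line where both are equal. Heme and iron genes lie mostly at positive values on both axes, mitosis genes near 0 in fetal cells and below 0 in adult cells, and 7 of 9 macrophage genes below 0 in fetal cells and above 0 in adult cells.

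Adult and fetal HSPCs differed in genes of the LIN28 and let-7 axis, which marks fetal blood cell production. HMGA2 was lower in adult HSPCs, at 13.9 ± 0.443 against 114 ± 3.1 CPM (SD, n = 2 each), a log2 fold change of -3.03 ± 0.33 (SE, edgeR adjusted p = 0.0181), and IGF2BP3 was lower by the same test (-3.56, edgeR adjusted p = 0.0382). LIN28B was at 2.21 ± 2.29 against 107 ± 27.7 CPM and IGF2BP1 at 7.03 ± 8.41 against 323 ± 89.3 CPM (n = 2 each). Their log2 fold changes of -5.65 and -5.54 passed only with the replicate block (edgeR adjusted p = 0.072 and 0.109, or 0.0264 and 0.0337 with the block). In adult HSPCs they were at 0.463% and 0.278% of the fetal level in the first series and at 4.48% and 5.11% in the second. Of the 11 genes of this list 2 fell (6 adjusted over the list alone, 5 with the block; camera adjusted p = 2.24e-07, adjusted p = 0.143 with an estimated correlation). By size, CHRNA6 (log2 7.30), LOC401097 (4.55), KIF21A (4.09) and CXorf57 (3.70) were higher in adult HSPCs, and STEAP4 (-5.64), the interleukin receptor IL7R (-4.69), the chemokine receptor CCR6 (-4.20) and MEG3 (-3.74) lower. The stem and progenitor list was higher in adult HSPCs, with 1 of 27 genes called higher (3 adjusted over the list alone, and 2 higher and 1 lower with the block; camera adjusted p = 4.15e-07, adjusted p = 0.143 with an estimated correlation).

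Some other HSPC genes passed only with the replicate block. CRHBP (2.62), GATA1 (1.13), MYB (0.65) and HBB (4.68) had edgeR adjusted p = 0.0662, 0.107, 0.231 and 0.208, or 0.0258, 0.0337, 0.0424 and 0.0171 with the block. MHC class II (0 of 11 called, 2 lower adjusted over the list alone, including HLA-DMB at -3.09, edgeR adjusted p = 0.127, or 0.02 with the block) had camera adjusted p = 5.73e-08, and adjusted p = 0.355 with an estimated correlation. Macrophage genes (0 of 9 called, 8 lower adjusted over the list alone) included MRC1 at 10.5 ± 1.81 in adult and 244 ± 64.8 CPM in fetal HSPCs (log2 -4.54, edgeR adjusted p = 0.0619, or 0.0241 with the block) and SIGLEC1 (-5.73, edgeR adjusted p = 0.161), which did not pass with the block either (0.0584). SIGLEC1 and CD14 moved to -12.6 and -4.87 without adult HSPC replicates 3 and 4, SIGLEC1 against 0 counts, which gives no size. The macrophage list had camera adjusted p = 1.7e-06, and adjusted p = 0.37 with an estimated correlation. Granulocyte and monocyte genes (0 of 21 called, 0 adjusted over the list alone) included CSF1R (-3.34, edgeR adjusted p = 0.157, or 0.034 with the block) and CD14 (-3.23), which did not pass with or without the block, with camera adjusted p = 3.31e-05 and adjusted p = 0.592 with an estimated correlation. Erythroid transcription factors (0 of 17 called, 4 higher adjusted over the list alone) had camera adjusted p = 0.000556, and adjusted p = 0.355 with an estimated correlation. With the block, 4 MHC class II, 1 macrophage and 4 granulocyte and monocyte genes were lower and 3 erythroid transcription factors higher.

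In total 16 genes were higher and 25 lower in adult than in fetal HSPCs by edgeR, 199 and 368 with the replicate block by series, and 786 and 1072 with the 16 libraries counted separately. DESeq2 called 215 and 423, and 1617 genes had an unadjusted edgeR p under 0.05. In simulated data for this comparison, without a series difference, 6 of 82 genes changed 2-fold, 42 of 59 changed 4-fold and 58 of 59 changed 8-fold were recovered. No gene passed with edgeR in a fit of these 2 groups alone (1500 at an unadjusted p under 0.05), or without fetal HSPC replicates 1 and 2 (1192), adult HSPC replicates 1 and 2 (1359) or adult HSPC replicates 3 and 4 (1312). Each named call was therefore lost in those fits, and 10 genes were higher and 10 lower without fetal HSPC replicates 3 and 4. Leaving out fetal HSPC replicate 1, fetal HSPC replicate 2 or adult HSPC replicate 1 left 16, 15 and 15 genes lower.

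ProEs differed more between the stages. The mitosis list was lower in adult ProEs, with 21 of 23 genes called lower (22 adjusted over the list alone). KIF20A was at 23.5 ± 3.92 in adult and 75.4 ± 8.29 CPM in fetal ProEs (SD, n = 3 each), a log2 fold change of -1.68 ± 0.18 (SE, edgeR adjusted p = 0.00141), and cyclin CCNB1 changed by -1.32. Of 23 DNA replication genes 12 were lower (19 adjusted over the list alone), including UHRF1 (-1.12) and the thymidylate synthase TYMS (-0.93). The LIN28 and let-7 axis was lower in 8 of 11 genes (9 adjusted over the list alone), with IGF2BP3 at -3.83, HMGA2 at -2.20, LIN28B at -4.38 and IGF2BP1 at -4.35 (edgeR adjusted p = 0.00141, 0.00196, 0.0127 and 0.0206). In camera these lists had adjusted p = 1.07e-15, 6.24e-10 and 8.17e-07, against adjusted p = 0.1, 0.153 and 0.1 with an estimated correlation. Of the DNA replication genes, 20 were lower with the replicate block. LIN28B and IGF2BP1 were not equally low in all adult ProEs: in the first series they were at 0.518% and 0.478% of the fetal level, and in the second at 9.39% and 7.96%.

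Part of the erythroid genes were called higher in adult ProEs, and no list of them passed with an estimated correlation. Of 17 erythroid transcription factors 10 were higher and 0 lower (11 and 1 adjusted over the list alone), among them BCL11A, a repressor of fetal hemoglobin, at 44.4 ± 24.7 against 10.8 ± 2.98 CPM (n = 3 each; log2 2.04, edgeR adjusted p = 0.0169), and GATA1 (0.77, edgeR adjusted p = 0.0395). KLF1 (0.82) passed only with the replicate block (edgeR adjusted p = 0.0805, or 0.0362 with the block). Of 21 heme and iron genes 7 were higher and 0 lower (12 and 0 adjusted over the list alone), including STEAP3 (1.09) and PPOX (edgeR adjusted p = 0.0034). By camera these lists had adjusted p = 2.12e-05 and 1.27e-05, against adjusted p = 0.153 and 0.419 with an estimated correlation. GATA2 was lower by the same test (-1.73, edgeR adjusted p = 0.00427), while MYB (-0.12) and CD34 (0.19) did not pass (edgeR adjusted p = 0.67 and 0.909). Of 17 p53 targets 6 were higher and 0 lower (6 adjusted over the list alone), including CDKN1A (1.56) and SESN2 (1.53), with camera adjusted p = 4.31e-05 and adjusted p = 0.1 with an estimated correlation. With the block, 12 transcription factors were higher and 1 lower, and 12 heme and iron genes and 10 p53 targets were higher.

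Granulocyte and monocyte genes were lower in adult than in fetal ProEs in 7 of 21 cases (14 adjusted over the list alone), including the integrin ITGAM (-3.77), CSF3R (-2.90) and S100A9 (-4.47; 77 ± 62.3 against 1698 ± 1033 CPM, n = 3 each). The genes named for the largest falls, MMP8 (-6.92), ORM2 (-6.13), CEACAM3 (-5.93) and CD177 (-5.69), are also expressed by granulocytes. Camera gave this list adjusted p = 8.7e-08, against adjusted p = 0.55 with an estimated correlation, and SPI1 (-1.73) passed only with the block (edgeR adjusted p = 0.131, or 0.00311 with the block). FMOD (6.71), IFI27 (6.35), TNXA (6.16) and ATPGD1 (5.84) showed the largest rises. Of 9 macrophage genes 3 were higher (6 adjusted over the list alone), C1QA, C1QB and C1QC (4.58, 4.45 and 4.25), but the list did not pass (camera adjusted p = 0.184, adjusted p = 0.735 with an estimated correlation). These 3 genes differed in the second series (4.98, 5.15 and 5.07) and little in the first (0.48, 0.27 and -0.28). Interferon genes were higher in 5 of 24 cases and immediate early genes in 5 of 18 (6 and 5 adjusted over each list alone). Camera called these lists (adjusted p = 0.025 and 0.0408, adjusted p = 0.666 for both with an estimated correlation), and the red cell membrane list (4 of 26 higher, 4 adjusted over the list alone; adjusted p = 0.0343, and 0.666 with an estimated correlation), but not with the replicate block (adjusted p = 0.0668, 0.112 and 0.0668). With the block, 16 granulocyte and monocyte genes were lower, 6 immediate early genes were higher and 1 lower, and 6 membrane genes were higher and 1 lower.

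For adult against fetal ProE, edgeR called 1282 genes higher and 1211 lower, 2400 and 2368 with the replicate block by series, and 2699 and 2607 with the 16 libraries counted separately. The sign was the same within both series for 2492 of these 2493 genes, but they were called from both series together, which largely sets that agreement. Across all 15522 genes tested, the log2 fold changes of the first and second series correlated at r = 0.723. Without fetal ProE replicate 3, fetal ProE replicate 4, adult ProE replicate 3 or adult ProE replicate 4, 569, 747, 847 and 658 genes were higher and 579, 695, 727 and 507 lower. ORM2, IGF2BP1, BCL11A and GATA1 each lost the call in at least 1 such fit (highest edgeR adjusted p = 0.0821, 0.0574, 0.0609 and 0.118). Camera with its preset correlation called 8 to 13 lists in other splits of the same 6 samples, against 15 in the real one. It called 8 to 11 in the 5 other splits with 1 first-series sample on each side. Each other split holds unequal numbers of adult and fetal samples on a side, so part of the stage difference remains in it. The splits therefore cannot tell how many lists would be called without a stage difference, and list calls at the preset correlation stay uncertain. Between the HSPC and ProE comparisons, 9 genes were higher in adult cells in both (1.3 for independent lists), 8 lower in both (2.0) and 3 opposite, with r = 0.31 across genes. These lists also rest on the same estimate of spread per gene, so they are not independent.

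Reads counted for globin genes made up 0.682% ± 0.17 of counts in adult and 1.72% ± 0.282 in fetal ProEs (SD, n = 3 each, exact two-sided permutation p = 0.1, adjusted p = 0.2 over 4 such tests). With 3 against 3 samples, 0.1 is the smallest p possible. The gamma share, HBG1 and HBG2 among the counts of beta-type globins, was 92.4% ± 4.25 in adult and 99.3% ± 0.349 in fetal ProEs (n = 3 each; exact permutation p = 0.1, adjusted p = 0.2). In HSPCs it was 22.8% ± 16.1 in adult and 92.2% ± 8.51 in fetal samples (n = 2 each; exact permutation p = 0.333, the smallest possible, adjusted p = 0.444). In the first and second series it was 11.4% and 34.2% in adult HSPCs, and 98.2% and 86.2% in fetal HSPCs. Whether carry-over between libraries of the second series contributed was not tested for globins. Globin was 0.212% ± 0.11 of adult and 0.262% ± 0.264 of fetal HSPC counts (n = 2 each; exact permutation p = 1). That difference changed sign to 0.137 percentage points without fetal HSPC replicates 1 and 2 and to 0.0281 without adult HSPC replicates 1 and 2. HBG1 and HBG2 were not called between the stages, in ProEs or in HSPCs. Between HSPCs their log2 fold changes were -2.03 and -1.95 (edgeR adjusted p = 0.449 and 0.48). They were -4.73 and -4.74 in the first series and 0.47 and 0.45 in the second. HBG1 reached 6671 ± 1105 CPM in fetal and 2559 ± 645.8 in adult ProEs (n = 3 each). Its rise during differentiation passed in adult cells (log2 3.73, edgeR adjusted p = 0.0168), as did that of HBG2 (3.59, edgeR adjusted p = 0.0189), but neither in fetal cells (3.08 and 3.13, edgeR adjusted p = 0.0698 and 0.0666). The fetal rises of HBG1 and HBG2 were 4.79 and 4.72 without fetal HSPC replicates 1 and 2, and 2.32 and 2.40 without fetal HSPC replicates 3 and 4. The interaction terms did not pass (0.65 and 0.46, edgeR adjusted p = 0.834 and 0.891). Both adult calls were lost without adult HSPC replicates 1 and 2 (edgeR adjusted p = 0.0727 and 0.0734), and both rises were 5.69 and 5.66 without adult HSPC replicates 3 and 4.

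Adult beta-globin HBB was at 947 ± 352 in adult HSPCs (n = 2), 274 ± 192 in adult ProEs (n = 3), 37.1 ± 31.1 in fetal HSPCs (n = 2) and 42.8 ± 35.2 CPM in fetal ProEs (n = 3). The fetal means rest largely on the second series, and carry-over of adult transcripts into its fetal libraries was not tested. Fetal HSPCs were at 15.1 CPM in the first series and 59.1 in the second, and fetal ProEs at 2.485 against 58.9 and 67.1. The adult change of -1.79 and the ProE stage difference of 2.69 passed only with the replicate block (edgeR adjusted p = 0.277 and 0.118, or 0.00888 and 0.00626 with the block). The fetal change was 0.20 (edgeR adjusted p = 0.947), but -2.39 within the first series and 0.09 within the second. Embryonic HBZ was lower in adult than in fetal ProEs (log2 -4.98, edgeR adjusted p = 0.0253), and HBE1 had no call in any comparison (edgeR adjusted p = 0.173 to 1). The embryonic and fetal globin list passed in fetal differentiation (0 of 4 called, 2 higher adjusted over the list alone, 0 with the block; camera adjusted p = 0.00482, 0.019 with the block and adjusted p = 0.37 with an estimated correlation). In adult differentiation 2 of 4 were higher (2 adjusted over the list alone) but the list did not pass (camera adjusted p = 0.0873, adjusted p = 0.587 with an estimated correlation), and its interaction did not either (adjusted p = 0.905). The same list, with 1 of 4 genes lower in adult ProEs (1 adjusted over the list alone), had camera adjusted p = 0.0289, adjusted p = 0.589 with an estimated correlation and 0.0784 with the replicate block. Between HSPCs it had camera adjusted p = 0.0157, adjusted p = 0.49 with an estimated correlation and 0.0671 with the block (0 of 4 called, 0 adjusted over the list alone). HBG1 with HBG2, and HBA1 with HBA2, are near-identical copies whose reads the counting could have split, so each single value is uncertain. Few reads were counted for the alpha globins: HBA1 was at 23.4 to 160 and HBA2 at 21.4 to 144 CPM in ProE samples. HBG1 was at 1814 to 7442 CPM there. Splitting between copies would not lower their sum. HBB, HBD and HBA1 were at 698, 256 and 89.8 CPM in adult HSPCs of the first series, and at 61.0, 64.1 and 23.4 CPM in its adult ProEs. In the second series they were at 1196, 480 and 165 CPM, then 432, 458 and 160 (replicate 3) or 329, 349 and 127 (replicate 4). Whether the counting lost reads of alpha globins, HBB or HBD was not tested. The globin shares, the gamma shares and the changes of HBB therefore hold only for the reads counted.

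**Figure D3:**
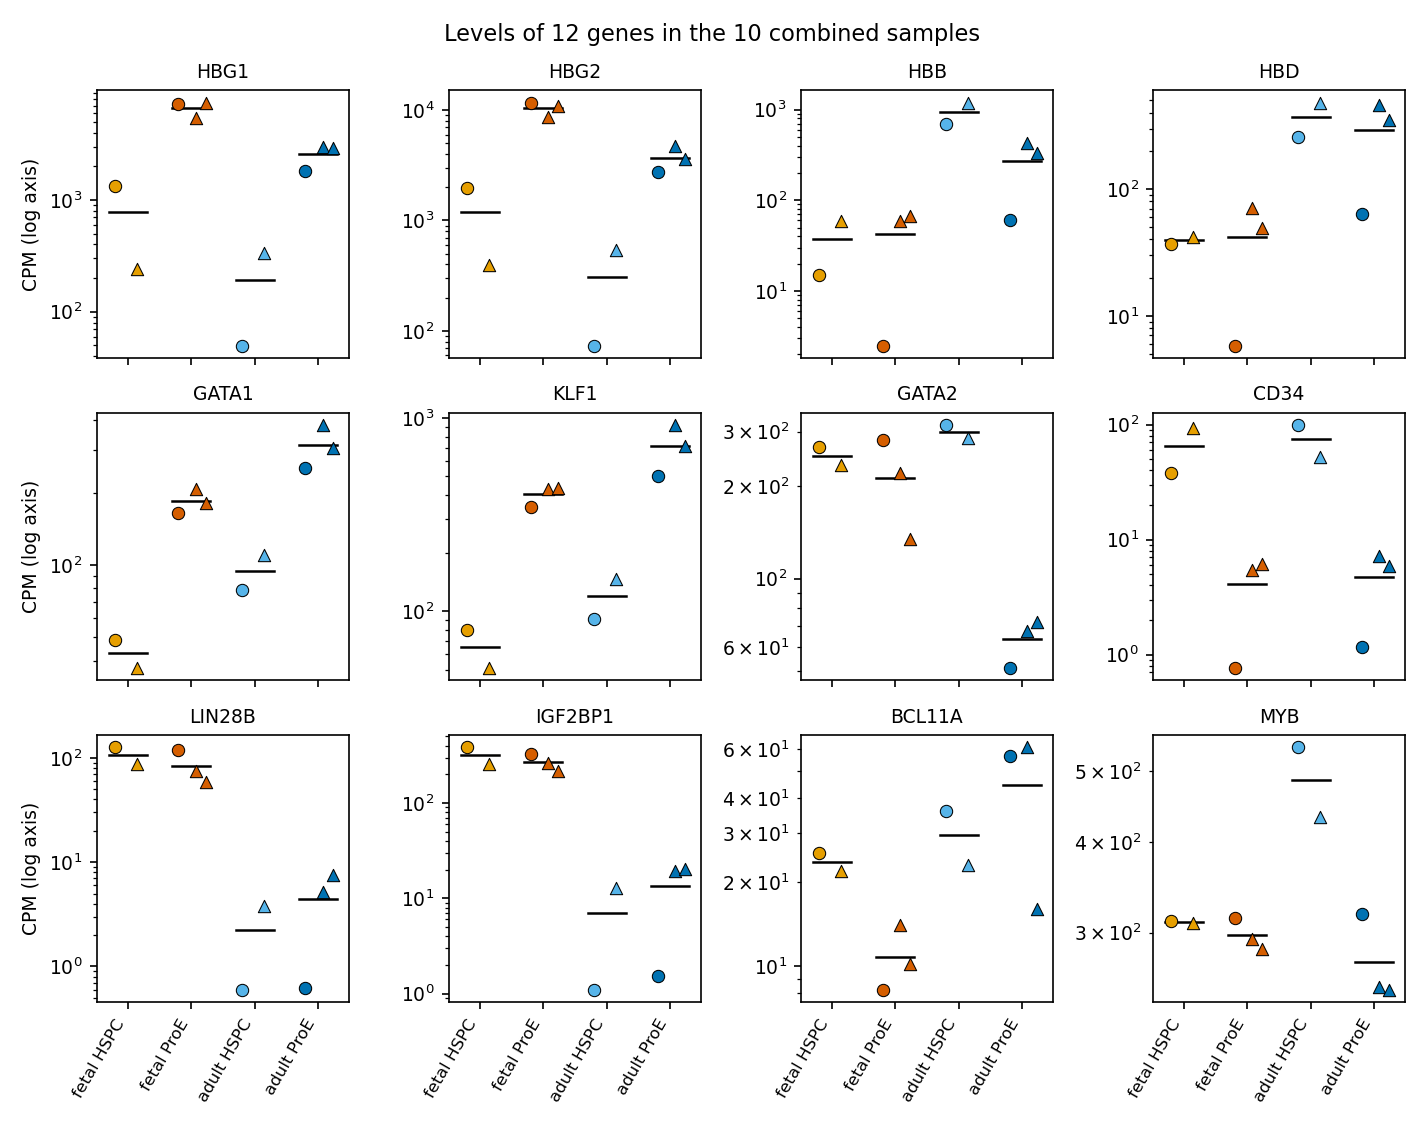
CPM on a log axis of 12 genes in the 10 combined samples, with 1 point per sample (circles, first series; triangles, second series) and a bar at each group mean. HBG1 reached a mean of 6671 CPM in fetal and 2559 CPM in adult ProEs, and LIN28B and IGF2BP1 were lower in the adult circles than in the adult triangles.

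The interaction compares the adult change from HSPC to ProE with the fetal one. Complement genes C1QB and C1QC, expressed by macrophages, rose in adult and not in fetal differentiation, with interaction terms of 8.93 ± 1.65 and 8.77 ± 1.69 (log2, SE; edgeR adjusted p = 0.042 and 0.0426). Next were HSPA7 (7.40), of the HSP70 family, and the interferon-induced IFI27 (7.12). CYP4F3 (-5.24), N4BP3 (-5.05), LOX (-4.98, or -3.11 without adult HSPC replicates 3 and 4) and FAM174B (-4.34) were the most negative. Mitosis genes had a lower term in 5 of 23 cases (21 adjusted over the list alone), including KIF20A (-1.61) and CCNB1 (-1.35), and DNA replication genes in 1 of 23, UHRF1 (-1.25; 13 adjusted over the list alone). Macrophage genes had a higher term in 3 of 9 (8 adjusted over the list alone). Camera gave adjusted p = 4.83e-16, 7.9e-12 and 3.21e-05 for these lists, against adjusted p = 0.142, 0.176 and 0.389 with an estimated correlation. MHC class II genes passed as a list with higher terms (0 of 11 called, 5 adjusted over the list alone; camera adjusted p = 3.55e-05, adjusted p = 0.389 with an estimated correlation). With the replicate block, 21 mitosis and 12 DNA replication genes had a lower term, and 7 macrophage and 5 MHC class II genes a higher one.

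The interaction was called for 151 genes with a higher and 74 with a lower term by edgeR, 771 and 743 with the replicate block by series, and 1546 and 1461 with the 16 libraries counted separately. In simulated data for this comparison, without a series difference, 2 of 82 genes changed 2-fold, 19 of 59 changed 4-fold and 45 of 59 changed 8-fold were recovered. No gene passed with edgeR without fetal ProE replicate 3 (2023 at an unadjusted p under 0.05), adult ProE replicate 4 (2051) or adult HSPC replicates 1 and 2 (2202), nor when ProE replicates 3 and 4 were combined too (1920), so every named term lost its call there. DESeq2 on all samples called 651 and 483. Without fetal ProE replicate 4, adult ProE replicate 3, fetal HSPC replicates 1 and 2, fetal HSPC replicates 3 and 4 or adult HSPC replicates 3 and 4, 29, 11, 23, 15 and 15 genes had a higher and 7, 2, 1, 1 and 4 a lower term, and without adult ProE replicates 1 and 2, 288 had a higher term. In total camera called 15 of the 25 lists for the interaction. The red cell membrane list (1 of 26 higher, 2 adjusted over the list alone, 2 with the block) had camera adjusted p = 0.0417, or 0.0677 with the block and adjusted p = 0.697 with an estimated correlation.

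**Figure D4:**
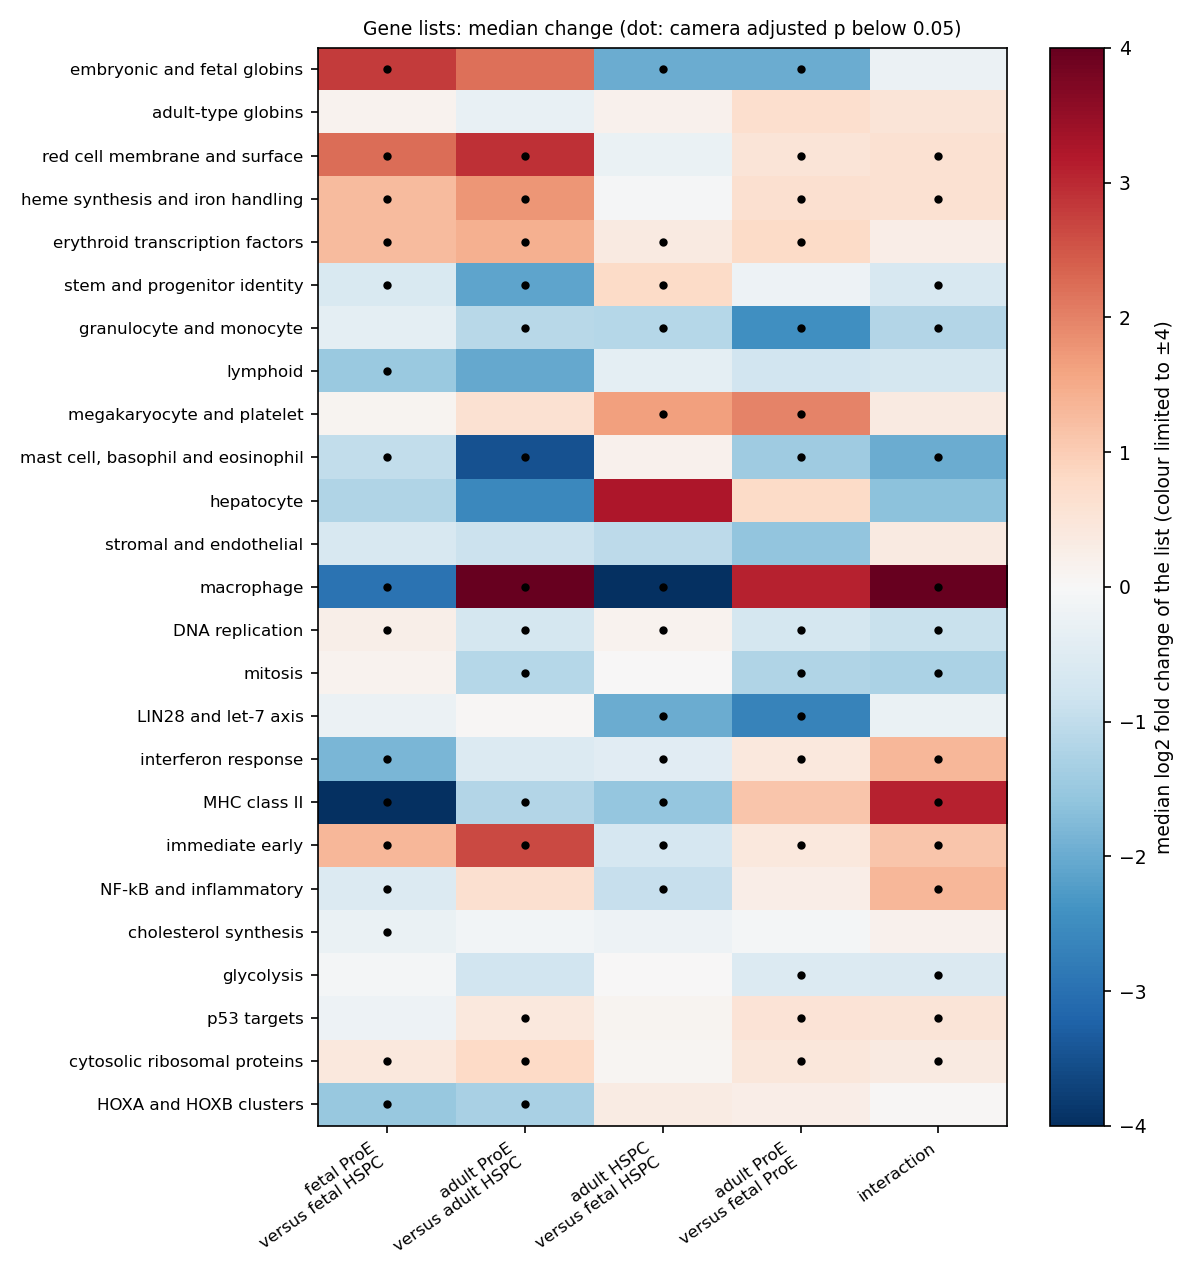
Median log2 fold change of each of the 25 gene lists (vertical axis) in the 5 comparisons (horizontal axis), shown as colour limited to 4 in either direction, with a dot where camera's adjusted p with the preset correlation was below 0.05. With an estimated correlation 0 of the lists passed in each comparison.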

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

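The tests of the series, of scaling between libraries and of other splits of the samples were chosen only after the result was seen.

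For 20 of the 79 named genes reported, the change from HSPC to ProE differed between adult and fetal cells by the edgeR interaction test, which is why each is listed here. The term was positive for 9: the complement genes C1QB (8.93) and C1QC (8.77), HSPA7 (7.40), the interferon-induced IFI27 (7.12), the mannose receptor MRC1 (6.34), STEAP4 (5.61), ATPGD1 (5.41), the chemokine receptor CCR6 (4.51) and the antiproliferative BTG2 (2.82). It was negative for 11: CYP4F3 (-5.24), N4BP3 (-5.05), the matrix enzyme LOX (-4.98), FAM174B (-4.34), HIF3A (-3.98), LOC401097 (-3.57), CRHBP (-3.50), CXorf57 (-2.88), KIF20A (-1.61), cyclin CCNB1 (-1.35) and UHRF1 (-1.25). All 20 also passed in the fit with the replicate block by series. C1QB, C1QC, HSPA7, IFI27, CYP4F3, N4BP3, LOX and FAM174B were named for the largest called terms, so they passed by selection. The others were named by size or adjusted p in the same data. Among all 15522 genes tested 225 passed, so 20 of 79 does not measure how common such terms are. Leaving out adult HSPC replicates 3 and 4 reduced LOX to -3.108, and no other single library or combined pair moved the log2 value of any of the 20 terms by over 1.5 times. That limit is wide for large terms: C1QB reached 10.3 without adult HSPC replicates 3 and 4. None of the 20 kept its call without fetal ProE replicate 3 or without adult ProE replicate 4. A test for single outlying samples was not applied, since the groups hold 2 or 3 combined samples.

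As a list, macrophage genes moved down from HSPC to ProE in fetal cells (camera adjusted p = 0.0417, 1 of 9 called) and up in adult cells (camera adjusted p = 0.00872, 5 of 9 called), but neither passed with an estimated correlation (adjusted p = 0.681 and 0.587), nor the fetal one with the replicate block (0.0918). A difference between the series cannot be the whole cause: 7 of 9 genes moved this way within both series in fetal cells and 8 of 9 in adult cells. In adult ProEs, macrophages in the samples may be a source, as 23 of 28 further macrophage genes had a higher mean than in adult HSPCs, 11 of them called. The abundant APOE (17.5 to 1015 CPM) and CTSL1 (10.6 to 259.7 CPM) are weak evidence, since their means were also higher in fetal ProEs (37.2 to 307.8 and 20.4 to 79.7 CPM). TYROBP, FCER1G and AIF1, which macrophages also express, were not higher there (25.8, 35.6 and 4.73 CPM, against 35.8, 40.8 and 24.2 CPM in adult HSPCs), and 17 of the 28 reached 10 CPM in both fetal ProEs and adult HSPCs. In fetal HSPCs 16 of 28 were higher than in fetal ProEs, with FPR3 called that way and APOC1 the opposite way (log2 3.55 toward ProE, edgeR adjusted p = 0.00481), so macrophages cannot be told apart there from progenitors that express these genes. These samples are labelled CD34+, a selection that would remove macrophages, whose completeness the labels do not give, and a stage difference stays open and untested.

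As lists, mitosis and DNA replication genes had lower interaction terms, and both fell in adult differentiation, at the preset correlation only: with an estimated correlation the adjusted p = 0.142 and 0.176 for the interaction and 0.163 and 0.255 for adult differentiation. In fetal differentiation the DNA replication list moved slightly up (median log2 0.23, camera adjusted p = 0.0329, 0.0156 with the replicate block and 0.616 with an estimated correlation). The lower depth of the second series does not explain the lower terms, as the median within the deeper first series was -1.28 with 23 of 23 genes below 0. Within the second series it was -1.31, and the DNA replication list had -0.954 and -0.911. Scaling does not explain them either: 1 factor per library shifts all genes alike, yet all 23 mitosis and all 23 DNA replication genes lay below the median interaction of all genes. Relative to it, the median of the mitosis list was -1.304 (quartiles -1.452 and -1.118) and that of the DNA replication list -0.92 (quartiles -1.024 and -0.732). A difference between the stages stays open, and no biological explanation was tested.

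Between adult and fetal ProEs, the 6 combined samples make 10 splits, too few for a share below 0.05. In a fit of these samples alone, 1 of the 10, the real one, called 2254 genes, and the highest of the others called 0. For lists, 1 of 10, the real one, called 15, and the highest of the others called 13. The splits with 12 and 13 lists put both first-series samples on 1 side. The 5 other splits with 1 first-series sample on each side, as in the real one, called at most 11 lists and 0 genes. Every other split holds unequal numbers of adult and fetal samples on a side, so part of the stage difference remains in it. That can add list calls and widen the spread that limits gene calls. The other splits therefore do not show what would be called without a stage difference.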

How the results depend on the processing

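The fit of 16 separate libraries without a block was first planned as the main one and became an alternative after seeing the data. Combining ProE replicates 3 and 4 too, leaving out combined pairs, the replicate block by series (also within stage), the second series alone and the estimated correlation with that block were chosen after seeing the data. Of 289 summary values under 21 settings, 174 stayed within 1.5 times or on the same side of the threshold, 112 counts moved further and 3 tests newly passed. The cause was not tested except where fewer samples or genes explain it.

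For adult against fetal HSPC, edgeR called 16 genes higher and 25 lower. The count higher was 25 with library totals, 39 higher and 66 lower were called with no filter, and 10 and 14 at 5 CPM, where fewer genes were tested. DESeq2 called 215 and 423. With only these 2 groups edgeR called 0 and 0 (1500 at an unadjusted p under 0.05, DESeq2 on all samples 215 and 423). RPKM gave 73 and 149 (pseudocount 1), 28 and 43 (0.1), and 162 and 227 (pseudocount 1, no filter). The overlap of the stage comparisons, 17 genes in the same direction, became 27 (library totals), 41 (no filter), 258 (DESeq2), 69 (RPKM, pseudocount 1, with or without filter) and 28 (RPKM, 0.1).

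Elsewhere, 397 genes were lower in fetal differentiation at 5 CPM. DESeq2 gave 865 higher and 1019 lower in fetal differentiation, 1826 lower for ProEs, 651 and 483 for the interaction and an overlap of 1142 for differentiation. RPKM gave the interaction 300 and 165 (pseudocount 1) or 283 and 174 (no filter). DESeq2 was not run for lists. The estimated correlation called 0 lists in each of the 5 comparisons, with and without the replicate block by series (camera, lowest adjusted p = 0.1).

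With 16 libraries and the replicate number as replicate block, the counts were 3193 and 3222 (fetal differentiation), 4455 and 4645 (adult), 1799 and 1750 (HSPC), 3863 and 3718 (ProE) and 2607 and 2756 (interaction), with overlaps of 4103 and 1508. The block within stage gave 3115 and 3212, 4459 and 4610, and 2597 and 2649 (interaction). Without a block, the 16 libraries gave 1764 and 2202, 3336 and 3559, 786 and 1072, 2699 and 2607, and 1546 and 1461, with overlaps of 2520 and 778. Counting near-identical libraries as separate shrinks the spread. Globin and gamma shares of the 16 libraries then differed by -1.14 and -5.75 percentage points in ProEs and the gamma share by -69.4 in HSPCs (exact permutation adjusted p = 0.0381 each).

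With the replicate block by series on the 10 samples, the counts were 1101 and 1484, 2918 and 3237, 199 and 368, 2400 and 2368, and 771 and 743, with overlaps of 1709 and 260. All genes called without the block were also called with it, and among the named genes reported and the lists the block changed the calls given beside the results, HLA-DRB1 between HSPCs (edgeR adjusted p = 0.109, or 0.0436 with the block), and no other call. The series block within stage gave 1179 and 1636 (fetal), 2912 and 3254 (adult), and 771 and 669 (interaction). With ProE replicates 3 and 4 combined, so with fewer samples, edgeR called 70 and 43, 1080 and 1043, 0 and 0 (HSPC, 1497 at an unadjusted p under 0.05), 230 and 171, and 0 and 0 (interaction, 1920 at an unadjusted p under 0.05, while DESeq2 on the 10 samples called 651 and 483), with overlaps of 82 and 0. The second series alone gave 800 and 1102 (fetal), 274 and 431 (HSPC), 1994 and 2089 (ProE) and 699 and 610 (interaction), with overlaps of 1135 and 315. It has 1 sample per HSPC group, assumed to vary like the ProE samples.

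Leaving out 1 library or combined pair, edgeR called 132 to 431 genes higher and 187 to 605 lower in fetal differentiation (9 to 16 lists), 712 to 1791 and 811 to 1952 in adult differentiation (13 to 17), 0 to 22 and 0 to 35 in HSPCs (9 to 18), 569 to 1309 and 507 to 1211 in ProEs (12 to 16), and 0 to 288 and 0 to 101 for the interaction (11 to 16). The lowest counts for HSPCs and the interaction, 0, came with 1192 and 2023 genes at an unadjusted p under 0.05 (DESeq2 on all samples, 215 and 651 higher). The globin share differed by -0.236 to 0.137 percentage points in HSPCs, changing sign without fetal HSPC 1 and 2 (0.1366) and without adult HSPC 1 and 2 (0.0281). In ProEs it differed by -1.195 to -0.925, and the gamma share by -80.7 to -58.03 in HSPCs and -9.31 to -5.41 in ProEs. Of the named genes' values, 1324 stayed the same, 172 lost the call, 1 gained it and 20 changed sign. Leaving out 1 library of a combined pair keeps that sample with fewer reads, so those fits could change little and add to the values that stayed the same. Where only 1 sample of a group remained, it was assumed to vary like the others.

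Among all called genes, 5 between ProEs and 1 for the interaction changed sign under each of the 3 RPKM settings. For the named genes reported, changes of sign were in values without a call, except HBE1 below. HBB in fetal differentiation was -0.456 (RPKM, pseudocount 1, both filters), -0.529 (0.1), -0.829 and -1.127 (16 libraries with the replicate block, and within stage), -0.183 (16 libraries), -0.198 (ProE 3 and 4 combined), -0.633 and -1.07 (series block, and within stage), -0.111 and -0.288 (without fetal ProE 3 or 4) -0.478 (without fetal HSPC 1 and 2) and at most 1.488 (without fetal HSPC 3 and 4). HBE1 in adult differentiation was -0.093 (16 libraries with the replicate block), -0.123 (16 libraries), -0.106 (ProE 3 and 4 combined), -0.236 (second series), -0.206 and -0.128 (without adult ProE 3 or 4) -0.765 (without adult HSPC 1 and 2) and at most 3.335 (without adult HSPC 3 and 4).

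Between HSPCs, the second series gave HBG1 0.48, HBG2 0.458, CD34 -0.83 and HBE1 3.059, the last one called (edgeR adjusted p = 0.00164). With all samples HBG1, HBG2, CD34 and HBE1 were -2.03, -1.95, 0.21 and -0.12, and BCL11A and SPI1 were 0.32 and -0.56, without a call. HBE1 was also 1.032 (without fetal HSPC 1), 0.015 (without adult HSPC 3), 2.12 (without fetal HSPC 1 and 2), 0.816 (without adult HSPC 1 and 2) and at the lowest -3.294 (without adult HSPC 3 and 4). Without fetal HSPC 1 and 2, CD34 was -0.291, and without adult HSPC 1 and 2, CD34 was -0.331 and BCL11A -0.034. SPI1 was 0.304 without fetal HSPC 3 and 4 and -1.101 without fetal HSPC 1 and 2. At the other end, CD34 was 0.991 (without fetal HSPC 3 and 4) and BCL11A 0.587 (without adult HSPC 3 and 4). In fetal differentiation, IGF2BP1 was -0.522 and SPI1 0.475 without fetal HSPC 3 and 4, and they were 0.05 and -0.929 without fetal HSPC 1 and 2, with SPI1 0.024 (without fetal ProE 1 and 2). CD34 between ProEs was -0.301 and -0.048 (without adult ProE 3 or 4) -0.402 (without fetal ProE 1 and 2) and at most 0.77 (without adult ProE 1 and 2).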

Other observations

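The tests of carried-over transcripts on genes chosen per cell type and of the depth of the second series were added after the first choice of genes or the result was seen.

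Several gene programmes outside the main comparisons also moved. The 77 ribosomal protein genes had a median log2 fold change from HSPC to ProE of 0.80 in adult cells and 0.42 in fetal cells. In fetal cells 0 passed by edgeR (0 adjusted over the list alone, 1 with the replicate block by series). In adult cells 5 rose (0 adjusted over the list alone, 58 with the block), including RPL14 (1.07) and RPS27 (1.25). Both lost the call without adult HSPC replicates 1 and 2 (highest edgeR adjusted p = 0.13 and 0.213). Camera called the list in both (adjusted p = 8.71e-09 and 2.73e-07), against adjusted p = 0.592 and 0.681 with an estimated correlation. Between adult and fetal ProEs, 0 of the 77 passed by edgeR (20 higher with the block) but the list did (camera adjusted p = 0.000127, adjusted p = 0.727 with an estimated correlation).

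Megakaryocyte and platelet genes were higher in adult than in fetal ProEs in 5 of 15 cases and lower in 1 (7 and 1 adjusted over the list alone), including the adhesion protein VWF (log2 3.33) and the platelet chemokine PPBP (3.43). NBEAL2 (-1.36) was lower. The list had camera adjusted p = 0.0024, and adjusted p = 0.666 with an estimated correlation. Mast cell, basophil and eosinophil genes were lower in 4 of 15 (6 adjusted over the list alone), including HDC (-2.57), with camera adjusted p = 0.000127, and adjusted p = 0.55 with an estimated correlation. Glycolysis genes were lower in 7 of 18 and higher in 2 (8 and 3 adjusted over the list alone), including LDHA (-1.76), with camera adjusted p = 0.0251, and adjusted p = 0.666 with an estimated correlation. Cholesterol synthesis genes shifted slightly in fetal differentiation (median log2 -0.26, 0 of 22 called, 0 adjusted over the list alone and 2 with the block; camera adjusted p = 0.0421, adjusted p = 0.305 with an estimated correlation). NF-kB and inflammatory genes fell there in 2 of 16 (5 adjusted over the list alone, 6 with the block; camera adjusted p = 0.0134, adjusted p = 0.305 with an estimated correlation). MHC class II genes fell in adult differentiation in 1 of 11 (1 adjusted over the list alone, 7 with the block; camera adjusted p = 0.00761, adjusted p = 0.587 with an estimated correlation). Adult-type globins (camera adjusted p = 0.107 to 0.913), hepatocyte genes (0.0975 to 0.849) and stromal and endothelial genes (0.0981 to 0.856) were called as lists in 0 of the comparisons at the preset correlation. With the replicate block by series, camera also called adult-type globins, cholesterol synthesis and ribosomal proteins between HSPCs (adjusted p = 0.0457, 0.0491 and 0.0123, against 0.107, 0.11 and 0.212 without it). At an estimated correlation without the block, camera gave these lists adjusted p = 0.5915, 0.4375 and 0.9275. The NF-kB, immediate early, interferon and megakaryocyte lists were called between HSPCs without 1 called member each (0 of 16, 18, 24 and 15, 2, 2, 1 and 0 adjusted over the list alone, and 2, 0, 3 and 0 with the block; camera adjusted p = 0.00015, 0.000556, 0.00503 and 0.00862, and adjusted p = 0.143, 0.501, 0.592 and 0.592 with an estimated correlation).

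Adult ProEs could be further along the erythroid programme than fetal ProEs. If so, the stage difference between ProEs would follow the differentiation change across genes. With differentiation taken from 1 series and the stage difference from the other, r across genes was 0.03 over 2612 genes and -0.099 over 2224 genes. Of the 939 genes at least 2-fold higher in first-series differentiation 61.2% were higher in adult ProEs of the second series, and 59.3% of the 1673 lower genes were lower. In the other direction the shares were 50.8% of 851 and 60.1% of 1373. The measures point different ways and do not decide it.

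LIN28B and IGF2BP1, nearly absent from adult samples of the first series, were detectable in those of the second. Carry-over of fetal transcripts into these libraries would put all genes absent from adult cells at 1 common share of the fetal level. No gene met the first choice, which asked for both cell types (0 genes), so that test is void. Genes were then chosen per cell type for lying under 1% of the fetal level in the adult sample of the first series, so their level there was fixed by the choice. Of these, 9 genes in ProEs, among them S100A8, S100A9, H19 and CD177, lay at 3.22% to 6.88% of the fetal level in the second series, with an upper quartile 1.296 times the lower quartile. LIN28B and IGF2BP1 lay at 9.39% and 7.96% in ProEs, and in HSPCs at 4.48% and 5.11%, against 0.463% and 0.278% in the first series. In HSPCs only 3 genes met the choice, and their quartile ratio of 9.622 rests on 1 of them, HLA-DQB1, at 55.9% of the fetal level. SIGLEC1 lay at 4.06% and the remaining gene at 2.17%. So few genes cannot tell whether HSPCs had 1 common share. A lower depth is no explanation, as 1 adult sample of the second series held 345 reads of IGF2BP1. Carry-over in the adult libraries of the second series may contribute to the level of these transcripts, but cells or samples that truly express them at that level cannot be told apart from it. Carry-over from adult into fetal libraries was not tested. HBB was at 59.1 CPM in fetal HSPCs and at 58.9 and 67.1 CPM in fetal ProEs of the second series. In the first series it was at 15.1 and 2.485 CPM, and adult HSPCs of the second series held 1196 CPM.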
